A study of Rattus norvegicus with 6 samples.

How the data were processed

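Total RNA from whole rat hearts was profiled on 6 one-colour arrays, 3 from hearts of rats that underwent cardiopulmonary bypass (CPB, in which a pump and oxygenator take over the circulation) and 3 from sham-operated controls, per the labels. The labels number the hearts 1 to 3 in each group and state no array type, scan, date, duration of bypass or sampling time. Every sample title also ends in the same number in brackets, whose meaning is not given. Each group was taken from the sample titles. The deposited table holds 1185 probes by 6 arrays with no missing value, and each array is 1 sample. All 6 sample columns of the table were used.

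The authors' processing is not given in the sources used here, so the scale of the deposited values was read from the values themselves. The deposited values are on a natural log scale. After undoing an inverse hyperbolic sine, a transform that for values of this size differs from a natural logarithm only by a constant, the distinct values of each array fell on an evenly spaced ladder, within 2.7e-06 of a step on every array. With base 2 the departures reached 0.5 of a step. The values thus fit whole steps of brightness with an offset and a scale for each array, put through such a transform. The method behind it is not stated, and the deposited values may already have been calibrated between arrays, so that values used as deposited are not necessarily unnormalized. Whether the authors filtered probes or subtracted a background is not given in the sources used here. The values are not centred and share no common floor. Values were divided by the natural logarithm of 2, and differences are given on the log2 scale.

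The lowest level of each array was taken as its floor. On sham 2 the lowest level held 52 probes and the next one 904, and the 2 lowest levels were taken as the floor there. Counts of probes above the floor measure how much of each array carried resolved signal. No depth in reads exists for arrays, and the number of arrays limits the precision.

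The probes carry IDs that begin with R or RG. The files do not pair these IDs with genes, and 0 of the 1185 IDs matched an identifier or symbol in the rat reference gene table (assembly GRCr8). The 24 gene lists that had been fixed for this tissue and treatment could not be applied, marker lists for other cell types included, and no gene set test was run. The rule for named items was the 10 probes per direction with the highest or lowest fold change among those passing the test, filled up by the smallest unadjusted p, with the always-named genes left out for want of names. Since the IDs cannot be read as genes, 2 IDs per direction are printed, the one with the lowest p and the one with the largest difference among those 10.

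Arrays were quantile normalized and probes were kept if they lay above the pooled 25th percentile, 8.27 on the log2 scale, on at least 3 of the 6 arrays, which left 556 probes. After quantile normalization this percentile was the value of probes at the floor, except those at the lowest level of sham 2, which lay below it. The probes above the floor on all 6 arrays were also normalized and fitted among themselves, as a separate set. CPB and sham were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 556 probes and an adjusted p threshold of 0.05. Also computed were the number of probes that differed at least 2-fold with no overlap between the groups, and the mean correlation between arrays within and between groups, with an exact permutation over the 10 splits of the 6 arrays into 3 and 3. No label says that the hearts came from separate litters or days, and p-values measure the spread between these 6 samples.

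The shared numbers were checked for pairing from correlations alone. Deviations from the group means correlated at 0.46 between CPB 1 and sham 1, at 0.11 between CPB 2 and sham 2 and at 0.57 between CPB 3 and sham 3 over the 556 probes. All were over 0.1, the minimum set for treating the numbers as pairs, the second by little. CPB 1 and sham 2, which differ in number, correlated at 0.12, so that pair 2 rests on a weak value. The pairing comes from these correlations and not from the labels. The fit with the replicate number as a block is given beside the unblocked one where it moved a count of probes by over 1.5 times, and for the counts of intervals.

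The procedure was tested on simulated data, 10 seeded simulations of the CPB and sham comparison with 200 probes changed in each. They kept the steps and floors of the real arrays. Each probe's brightness was the mean of its deposited values over the 6 arrays, floor values included, so that of a probe at the floors was not a measured one. On average 501 probes were tested in each. Of the changed probes that passed the filter, 14% were called at 2-fold, 61.6% at 4-fold and 83.1% at 8-fold. Of unchanged probes tested, 1.1% were called. The spread of each simulated probe was drawn from the real probes above the floor on all 6 arrays. Their median SE in the real fit was 0.42, against 0.64 for the 556 probes. Arrays of the same number shared no deviation. These shares may thus be too high for the real probes, and they hold for 200 changed probes. Simulations with no change called 0 of 5214 probes.

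Normalization, the filter, the variance model and each array in turn were varied one at a time. These alternatives and the comparison's design were fixed before the data were examined, except the 4 that deal with the floor or with the brightness steps, and the correlation limited to arrays of different number. Alternatives for a pseudocount were not run, since the values are already logarithms, nor were those for gene lists.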

Results

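The hearts of rats exposed to cardiopulmonary bypass were compared with those of sham-operated rats, 3 arrays per group, to find transcripts whose level differs after bypass. The keywords of the series name cytokines and inflammation as the subject. The probes are known here only by ID, and the comparison is therefore described by probe and not by gene.

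The arrays differed in how much of the 1185 probes they resolved. CPB 1 had 674 probes above its floor, CPB 2 had 451 and CPB 3 had 541. Sham 1 had 592, sham 2 had 229 and sham 3 had 649. Across the table, 192 probes (16.2%) lay above the floor on all 6 arrays and 311 (26.2%) on none. One brightness step was worth 1253 units on sham 2, against 170.8 on sham 3 and 226.7 to 431 on the other arrays. Sham 2 held 29 distinct values for its 1185 probes and sham 3 held 86. A low signal on sham 2 was therefore the least precise of the set. Probes with IDs beginning with R and with RG were resolved at similar rates, 56.4% and 57.6% on CPB 1 and 19.1% and 19.7% on sham 2. The widest gap was 56.6% against 52.2%, on sham 3.

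**Figure D1:**
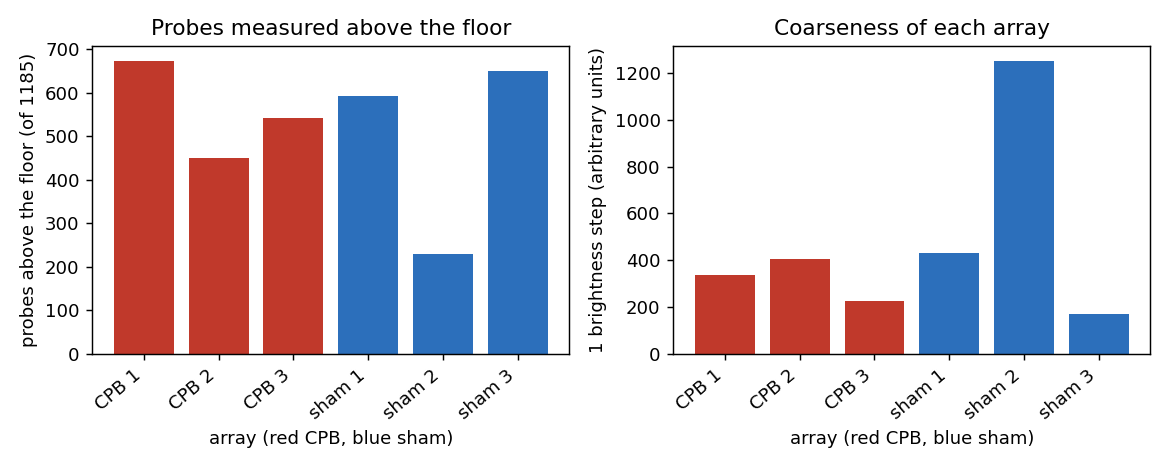
Left, number of probes above the floor on each array (red, CPB; blue, sham). Right, size of 1 brightness step on each array in arbitrary units, a larger step meaning coarser values. Sham 2 has the fewest probes above the floor (229) and the largest step (1253).

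No probe differed between CPB and sham hearts past the threshold. In limma's test 0 of 556 probes had an adjusted p under 0.05, and the lowest adjusted p was 0.989. At an unadjusted p under 0.05 there were 14 probes, 12 higher and 2 lower in CPB, where 27.8 are due by chance. With the replicate number as a block, limma gave 26 such probes, 18 higher and 8 lower in CPB, and again 0 after adjustment (lowest adjusted p 0.781). Without the block, the count of 14 became 4 without CPB 2 and 35 without sham 3, and it was 1 with the values as deposited and 3 with arrays scaled to the same 75th percentile. Of the 556 probes, 487 (87.6%) had a mean difference under 2-fold. The median 95% confidence interval reached 1.4 on the log2 scale to either side of the estimate. For probes at the floor on some arrays, the floor can make differences and intervals smaller or larger. No limit on a change is given for them. Normalization moved the floor of sham 2 from 10.36 to 8.27 on the log2 scale. R296 on CPB 3, dimmer at 9.65 as deposited, became 10.06.

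The 192 probes above the floor on all 6 arrays were normalized and fitted among themselves. This set leaves out any probe at the floor on an array, R296, RG270, R160 and RG291 of the next paragraphs included, and so cannot hold a change that reached the floor. In it 185 (96.4%) differed by less than 2-fold, and the differences ran from -1.22 to 1.18 on the log2 scale. The interval excluded a change of 4-fold or more for 172 of the 192, and for 180 with the replicate block. In limma's test 0 passed (lowest adjusted p 0.997), and 7 had an unadjusted p under 0.05, 2 higher and 5 lower in CPB, where 9.6 are due by chance. With the replicate block 14 had an unadjusted p under 0.05, 5 higher and 9 lower, and 0 passed after limma's adjustment (lowest adjusted p 0.562). This set was chosen after the values were seen.

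Before adjustment, the lowest p among probes higher in CPB belonged to probe R296. Its normalized level was 10.67 ± 0.58 in CPB and 8.61 ± 0.60 in sham (log2, mean ± SD, n = 3 each), a difference of 2.06 with an SE of 0.59 and a limma adjusted p of 0.989. It lay above the floor on 3 CPB arrays and on 1 sham array. Probe RG270 had the largest difference of the 556, 3.36 with an SE of 1.22 and a limma adjusted p of 0.989. Its level was 13.75 ± 1.72 in CPB and 10.39 ± 2.64 in sham (log2, mean ± SD, n = 3 each), and the groups overlapped, since sham 2 at 13.35 exceeded CPB 3 at 11.89. Between arrays of the same number, RG270 was higher in CPB by 5.80, 1.94 and 2.33 on the log2 scale. R296 was higher by 1.43, 2.95 and 1.79. RG270 lay at the floor on sham 1, and R296 on sham 2 and sham 3, so that 5.80, 2.95 and 1.79 are differences from the floor value and not from a measured level. With floor values counted as they stand after normalization, RG270 and R296 were 2 of the 4 probes at least 2-fold higher in CPB in all 3 numbered pairs. In the other direction, 0 probes were at least 2-fold lower in all 3. As deposited, R296 lay at 11.16 on CPB 2 and at the floor of 10.36 on sham 2. Its 2.95 thus depends on where normalization put that floor. When each array was scaled to the same median, RG270 was the 1 probe to pass the threshold, with a difference of 4.27 and a limma adjusted p of 0.021. On CPB 2, CPB 3, sham 1 and sham 2 the median is the floor itself, so this scaling lined up floors there and not signal. As deposited, RG270 lay at 11.78 on CPB 3 and at 13.3 on sham 2. The difference of RG270 was 5.17 without sham 2. That of R296 was 0.65 with brightness steps in place of the deposited values.

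Among probes lower in CPB, R160 had the lowest p, with a difference of -1.46, an SE of 0.63 and a limma adjusted p of 0.989. It lay above the floor on all 3 sham arrays and on 1 CPB array, with levels of 9.96 ± 0.93 in sham and 8.50 ± 0.40 in CPB (log2, mean ± SD, n = 3 each). As deposited, R160 lay at 9.80, 11.33 and 9.09 on sham 1, 2 and 3, where the floors were 8.84, 10.36 and 7.66. On CPB 1 it lay at 8.73, with a floor of 6.45. These are dim values, where the brightness steps are coarse. Probe RG291 had the largest difference in this direction, -1.92 with an SE of 1.03 and a limma adjusted p of 0.989. Its level was 9.43 ± 2.00 in CPB and 11.34 ± 1.58 in sham (log2, mean ± SD, n = 3 each). It too lay above the floor on 3 sham arrays and 1 CPB array. For both probes CPB 2 and CPB 3 were at the floor. Within the numbered pairs R160 differed by -0.34, -2.76 and -1.29 and RG291 by -0.84, -3.62 and -1.29, where the second and the third value of each are differences from the floor value. The difference of RG291 was -0.74 with a common floor for all arrays, and that of R160 was -0.69 with brightness steps.

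**Figure D2:**
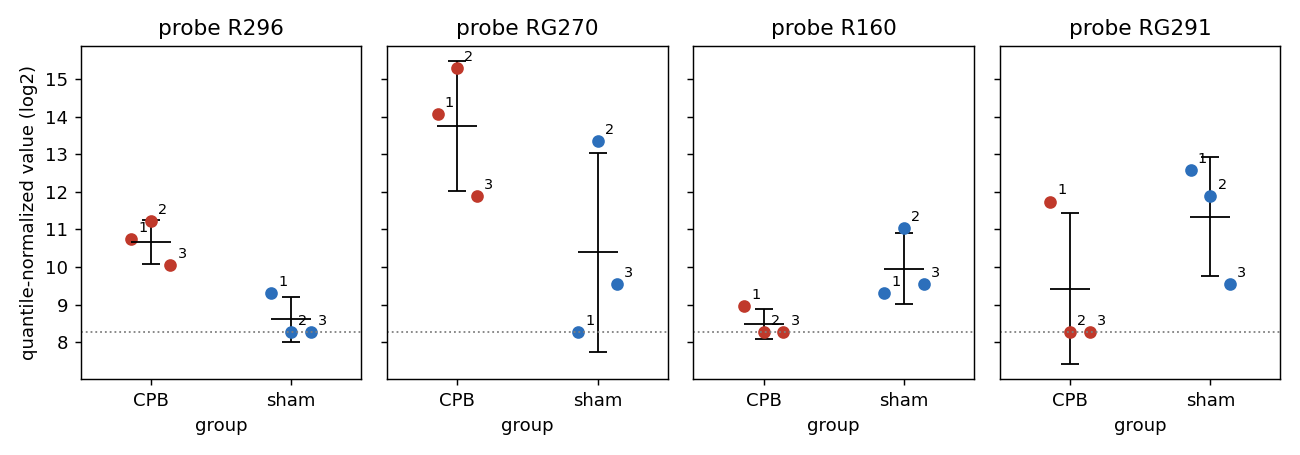
Quantile-normalized level (log2) of 4 probes on each array (points, labelled with the replicate number), with the mean and SD of each group (bars, n = 3). The dotted line is the floor value, 8.27. None of the 4 passed the adjusted threshold, and several points lie on the floor.

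Counting without a variance model, 19 of the 556 probes differed at least 2-fold with no overlap between the groups, 12 higher and 7 lower in CPB. This count became 80 without sham 3, 42 without CPB 3, 41 without sham 1 and 38 without CPB 1, where 3 arrays face 2. It was 7 with arrays scaled to the same 75th percentile and 2 with brightness steps. Among the 192 probes above the floor on all 6 arrays it was 3, with 1 higher and 2 lower in CPB. In all, 34 probes (6.1%) had no overlap, where chance gives up to 10% for 3 arrays against 3. Of probes above the floor on every array of one group and on none of the other, 2 were detected in CPB and 0 in sham. The same count over the other 9 splits of the 6 arrays ranged from 2 to 24. The other splits that part all 3 numbered pairs gave 5, 2 and 2.

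The direction of the differences as a whole depended on the scaling and on which probes were kept. After quantile normalization 61.5% of the 556 probes were higher in CPB and 37.8% lower, with a median difference of 0.16. With the values as deposited 15.4% of the 1159 probes then kept were higher and the median was -0.89. With arrays scaled to the same median 88.3% of the 479 probes then kept were higher and the median was 0.64. The array median used there is the floor on CPB 2, CPB 3, sham 1 and sham 2. With quantile normalization and no filter 43.5% of 1185 probes were higher, and with the filter on all 6 arrays 41.7% of 192. Without sham 2 the share was 46.6% and the median -0.07. Among the 192 probes above the floor on all 6 arrays, 52.1% were higher and 47.9% lower, with a median of 0.01. Simulated arrays with the same steps and floors and no change gave a median of 0.15 over the probes kept. A simulated probe's brightness was its mean deposited value, floor values included, and the floors differed between arrays. The 0.15 may depend on that setting and does not settle the source of the real shift.

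No closer resemblance within than between groups was shown. The mean correlation between arrays was 0.753 within groups and 0.774 between groups over the 556 probes. Of the 10 splits of the arrays, 7 gave a difference as large or larger (exact permutation p = 0.7, one-sided, the smallest possible being 0.1). Leaving out the correlations between arrays that share a number, with all arrays kept, turned the direction. The mean was then 0.740 between groups against the 0.753 within. Of the 4 splits that part all 3 numbered pairs, the real one gave the largest such difference (exact permutation p = 0.25, one-sided, the smallest that 4 splits can give). The closest arrays were CPB 3 and sham 3 (r = 0.934) and then CPB 1 and sham 1 (r = 0.863). These correlations are across probes, which are not independent replicates. The 2-fold count was higher than 19 for 5 of the other 9 splits. It was 80 for CPB 1, sham 1 and sham 2 against CPB 2, CPB 3 and sham 3. That split called 9 probes at an adjusted p under 0.05 in limma.

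**Figure D3:**
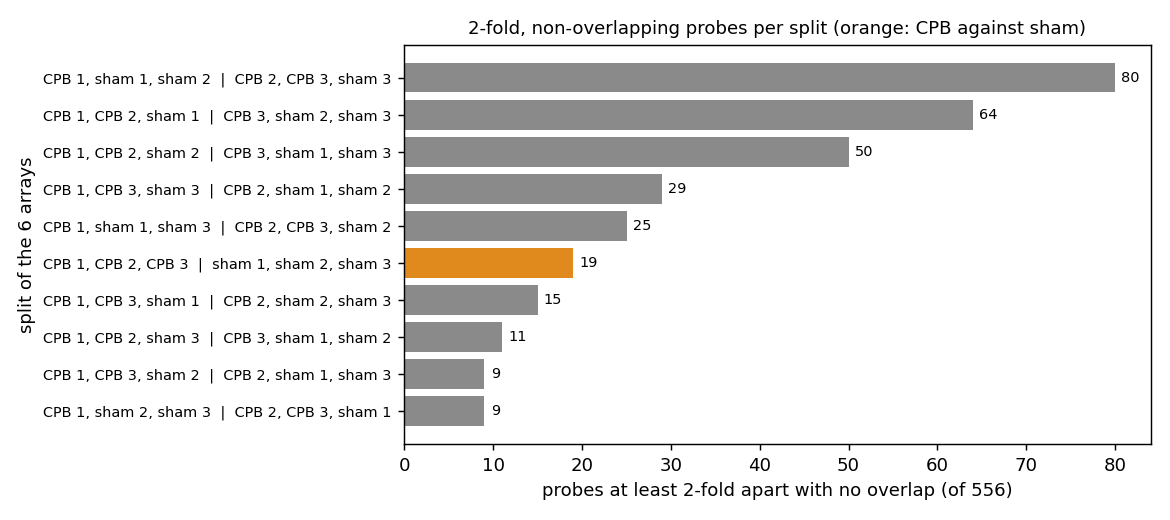
Number of probes at least 2-fold apart with no overlap (horizontal axis, of 556) for each of the 10 splits of the 6 arrays into 3 and 3. The comparison of CPB with sham (orange) gave 19 and other splits gave 9 to 80.

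Some wide differences between arrays crossed both groups. In the split that gave 80 probes, R301, R366 and R529 differed at least 16-fold with no overlap after normalization. R529 was among the 9 brightest probes on CPB 2, CPB 3 and sham 3, at 15.67, 15.56 and 15.78 (deposited values, log2). On CPB 1 it lay at the floor, 6.45, on sham 2 at the floor, 10.36, and on sham 1 at 9.80. R366 and R301 lay at 12.96 and 12.44 on CPB 2, at 14.10 and 12.94 on CPB 3 and at 14.08 and 13.46 on sham 3. Both were at the floor on CPB 1 and sham 2. Between CPB and sham R529 differed by 2.15 on the log2 scale, with a limma adjusted p of 0.989. These 3 probes were chosen after their values were seen.

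**Figure D4:**
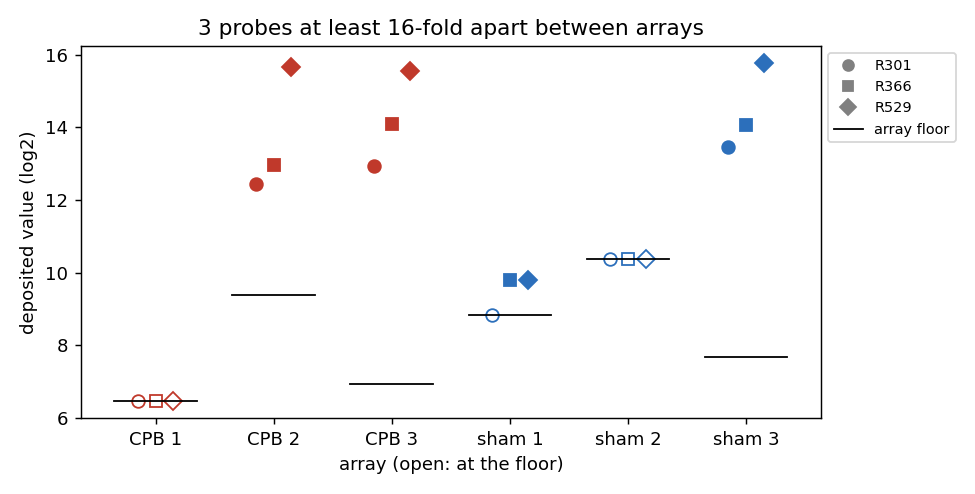
Deposited values (log2) of probes R301, R366 and R529 on each array (red, CPB; blue, sham; open symbols at the floor), with each array's floor as a line. The 3 probes are bright on CPB 2, CPB 3 and sham 3 and at or near the floor on CPB 1, sham 1 and sham 2.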

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

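The count of 0 probes past the threshold was the same under 21 of 22 alternatives. Arrays scaled to the same median gave 1 probe (RG270). That median is the floor on CPB 2, CPB 3, sham 1 and sham 2, and whether this gave the call was not tested. Leaving out each array in turn gave 0 to 0. The lowest adjusted p of each setting ran from 0.021 to 0.999. The replicate block kept the count at 0 and raised the probes with an unadjusted p under 0.05 from 14 to 26. It changed no call. Among probes above the floor on all 6 arrays, the block also gave 0 past the threshold and raised the unadjusted count from 7 to 14. Over all alternatives the unadjusted count ran from 1 to 35. The 19 probes at least 2-fold apart with no overlap became 7 with arrays scaled to the same 75th percentile, and 5 with the filter applied on all 6 arrays. Among alternatives chosen after seeing the data, the count was 3 among probes above the floor on all 6 arrays, 4 with a common floor and 2 with brightness steps. The filters on all 6 arrays and above the floor tested 192 probes in place of 556. Leaving out 1 array gave 27 to 80 such probes. By chance, 3 arrays against 2 overlap less often, but how much of the rise this gives was not tested. The highest, 80, came without sham 3, and the others over 1.5 times the 19 were 38 without CPB 1, 42 without CPB 3 and 41 without sham 1. The difference between within-group and between-group correlation was -0.022 and ran from -0.050 to 0.012 over its 11 alternatives. The highest was over arrays of different number only, an alternative chosen after seeing the data. The range includes -0.050 to 0.008 with 1 array left out. The 4 named probes kept their sign under every alternative that tested them, but not their size. R296 ran from 0.65 to 2.48, RG270 from 2.31 to 5.17, R160 from -1.89 to -0.69 and RG291 from -2.73 to -0.74. A filter at the median kept the same 556 probes, because both percentiles fall on the floor, and so tested nothing. Levels on the floor have no order, and the coarse steps of sham 2 limit what can be seen of dim probes.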

Other observations

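All tests in this part were chosen after the results were seen. CPB against sham gave 0 probes past the threshold, which all 10 splits of the 6 arrays must equal or exceed, so that this comparison tests nothing. The highest of the others gave 9. For probes with an unadjusted p under 0.05, 6 splits gave at least 14, the real value, and the highest other gave 73. For probes at least 2-fold apart with no overlap, 6 splits gave at least 19, and the highest other gave 80. With 10 splits the share can never fall under 0.05. Among the 4 splits that part all 3 numbered pairs, CPB against sham gave the highest 2-fold count, 19 against 11, 9 and 9. The other 6 splits part 1 pair and keep 2 together, and 5 of them gave 25 or more. The split with 80 does not follow the groups. It keeps CPB 1 with sham 1 and CPB 3 with sham 3, and parts only pair 2. No test separated it from the likeness of arrays of the same number.

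One pattern is that split itself, CPB 1, sham 1 and sham 2 against the other 3 arrays. Values at the array floors as its cause were tested on the 192 probes above the floor on all 6 arrays. There this split still ranked 1 of 10, with 13 probes against 10 for the next, which argues against the floors as the whole cause. Whether the arrays were made or hybridised in separate lots, or the rats differed in origin, stays open, since the labels give neither. No biological explanation was tested, because no group of the study follows this split.

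A second pattern is the near absence of R301, R366 and R529 from CPB 1, sham 1 and sham 2. Lower sensitivity of the 3 arrays without the signal would also lose other probes of that brightness. Of the 43 other probes at least as bright on CPB 2, CPB 3 and sham 3 (a mean of 12.95 or more, log2), 100% lay above the floor on each of CPB 1, sham 1 and sham 2. This argues against a general loss of probes of that brightness to the floor on these arrays. A weaker loss of signal was not tested, since only the place above the floor was counted. By that count R366 and R529 were themselves above the floor on sham 1, at 9.80. A candidate explanation is that the transcripts of R301, R366 and R529, or the part of the heart that holds them, differed between the rats. Another is a fault of these spots on some arrays. Neither was tested. A reader with the probe annotation would want to look up these 3 IDs first.

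Another pattern is that arrays with the same replicate number deviated together. Shared positions on the array floors might give this. Among the 192 probes above the floor on all 6 arrays, the correlations of deviations were 0.47, 0.27 and 0.56 for numbers 1, 2 and 3, so the lowest, 0.27, stayed over 0.1 and floors alone do not account for it. Arrays of different numbers there lay between -0.48 and 0.02. Deviations from a group mean cancel out within the group, so positive same-number values bring negative ones elsewhere on balance. The range for different numbers therefore adds no support for pairing. A shared day or lot for each number is a hypothesis that the labels cannot settle.

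Within the numbered pairs, 93 of the 556 probes (16.7%) differed in the same direction in all 3, 53 higher and 40 lower in CPB, where chance gives 25% if no values are tied. Pairs with both arrays at the floor are tied and lower this share. Among the 192 probes above the floor everywhere the share was 24%, with 20 higher and 26 lower.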
